A study of Mus musculus with 6 samples.

How the data were processed

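The series holds bulk RNA-seq of mouse ovarian granulosa cells in culture, 3 libraries of untreated cells and 3 of cells exposed to cyclophosphamide, an alkylating chemotherapy drug, for 24 h. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads, fragmented and copied with random hexamers. Per the submitters' processing notes, CASAVA and HISAT2 version 2.0.5 were used with the mouse build GRCm39. The counting tool, its strand setting and the annotation release are not given in the sources used here. Groups were taken from the treatment label. That label names intraperitoneal injection for the treated samples, while the treatment protocol and the design text describe drug added to cultured cells, and the exposure is given here as the latter state it. Nothing in the labels says that the replicates came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical, with variances moderated across genes.

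The deposited table is named as raw counts, yet its values are FPKM made by the authors (reads scaled by gene length and library size), as the values themselves show. They are not whole numbers and sum to between 275229 and 300505 per library. Multiplied by the gene length in the same table, 100% of the values in each library were whole multiples of 1 step, within a tolerance of 0.01 of a read, and that step gave the reads per gene. The recovered reads summed to 16458385, 17607586 and 17334754 in the untreated libraries and to 16689902, 17275338 and 16715499 in the cyclophosphamide libraries. The library size implied by the FPKM was 0.975 to 1.04 times the summed reads, so the authors' values carry a scaling between libraries whose method is not given in the sources used here. Gene coordinates in the deposited table were compared with GENCODE M21, an annotation of the build GRCm38. Of 54495 shared gene IDs, 98.3% had an equal start and end, although the processing notes name GRCm39. Coordinates are therefore given as the table has them and read as GRCm38. No column of per-sample values was left unused.

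The count-based tests planned before the data were examined were replaced by a test on the deposited FPKM, although the recovered reads would have allowed them. Each gene was tested with limma version 3.58.1 in R version 4.3.3 on log2(FPKM + 0.1), with a mean-variance trend, moderated variances and Benjamini-Hochberg adjustment, two-sided, at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes. Genes entered the test with the equivalent of 10 reads in at least 3 libraries and 15 reads in all. Of 54532 genes in the table, 27510 had a read in any library and 14755 were tested, and these held 99.9% of the reads. The fit was tested on simulated data for this comparison, with reads drawn for the same 14755 genes. It recovered 31.3% of 67 genes changed by 1.5-fold, 85.1% of 67 changed by 2-fold and 100% of 66 changed by 4-fold, with 9 false calls. The simulation changed only these genes and gave every gene the same fixed dispersion between libraries. In the real data 69.3% of genes were called, so these shares are not the power or error of the real comparison.

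Gene lists, 26 of pathways and 8 of markers of other cell types, were fixed before the data were examined. They were tested with camera in limma, which compares the genes of a list with all other genes, with a preset correlation of 0.01 between genes, on lists with at least 5 measured members. Adjustment ran over the pathway lists and over the marker lists separately. Camera was also run with the correlation estimated for each list. In that form its p-values rest on the few residual degrees of freedom of the libraries, not on the number of genes. A call lost there can therefore reflect low power and does not show that correlation between genes made the call. Of 678 symbols in the lists, 53 were matched to the older symbol in the table through RefSeq synonyms and 1 was not matched. Lists overlap, so their results are not independent.

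Genes are named by a rule fixed before the data were examined. It takes the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those past the threshold, with a mean of at least 5 CPM (reads scaled by library size alone) and no overlap between the groups. It adds a fixed panel of 16 genes and, for each list, the 2 called members with the smallest p-values not named already. Predicted genes were passed over, and not every gene that the rule takes is printed. Other members are named where few moved against their list or where a list had few members, and these were chosen after their values were seen.

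The alternatives were the replicate number as a block, size factors from the median of ratios or the upper quartile, no filter or a stricter filter (a mean of at least 1 CPM), leaving out each library in turn, limma-voom on the recovered reads, protein-coding genes only, a minimum of 2-fold, an adjusted p under 0.01, an estimated correlation and the fry test for lists. Pseudocounts of 0.5 and 1 and scaling to total reads were added after the data were seen. The replicate numbers did not pair the libraries, so the comparison was unpaired. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of at least 3.81, and none was taken as a duplicate.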

Results

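Polyadenylated RNA was measured in mouse ovarian granulosa cells, the somatic cells that surround the oocyte, after culture without treatment (3 libraries) or with cyclophosphamide for 24 h (3 libraries). The series title concerns serine and ferroptosis, an iron-dependent cell death by lipid peroxidation, and no library is labelled as given serine. Depth ranged from 16458385 to 17607586 reads per library, with 20940 to 21920 genes detected in each. The libraries separated by treatment on the first principal component, which held 87.2% of the variance. Correlations of log2 values were 0.989 to 0.991 among untreated libraries, 0.987 to 0.992 among cyclophosphamide libraries and 0.898 to 0.909 between the groups. On the second component (4.55%), cyclophosphamide replicate 1 lay at -27.4 and replicates 2 and 3 at 20.1 and 6.29.

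The 6 genes that rose most with cyclophosphamide were Trib3, Mt2, Slc7a11, Gdf15, Ddit3 and Hmox1. Trib3, a pseudokinase induced by amino acid and endoplasmic reticulum stress, rose from 4.50 ± 0.40 to 189 ± 1.69 FPKM (SD, n = 3), a log2 fold change of 5.36 ± 0.07 (SE). Slc7a11, the cystine importer that feeds glutathione synthesis and restrains ferroptosis, rose from 1.23 ± 0.05 to 50.8 ± 5.37 FPKM, a log2 fold change of 5.25 ± 0.10. Gdf15, Ddit3 and Hmox1, which encode a stress cytokine, the transcription factor CHOP and the heme-degrading heme oxygenase, rose by 4.70 ± 0.10, 4.42 ± 0.06 and 4.38 ± 0.12 on the log2 scale. The metallothionein gene Mt2 rose by 5.26 ± 0.51, with untreated values of 0.62, 0.78 and 3.32 FPKM, and without untreated replicate 3 its log2 fold change was 5.96. With a pseudocount of 1, the values of Mt2 and Slc7a11 were 4.45 and 4.53.

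The 6 genes that fell most were Ctgf, Thbs1, Gdf6, Gna14, Inhbb and Prss23. Ctgf, a matricellular growth factor gene, fell from 193 ± 16.3 to 3.35 ± 1.45 FPKM (SD, n = 3), a log2 fold change of -5.88 ± 0.24 (SE). Thbs1, which encodes thrombospondin 1, fell from 1993 ± 46.2 to 47.1 ± 22.5 FPKM (log2 fold change -5.50 ± 0.28). Inhbb, the beta B subunit of inhibin and activin, had a log2 fold change of -4.90 ± 0.18, and the protease gene Prss23 one of -4.85 ± 0.23. Gdf6, a bone morphogenetic protein gene, and Gna14, a G protein alpha subunit gene, had values of -5.35 ± 0.18 and -5.28 ± 0.23. These last values depend on the pseudocount and the method, since the cyclophosphamide libraries held 4 reads of Gdf6 and 9 of Gna14 in all, and they were -3.35 and -3.48 with a pseudocount of 0.5, -2.51 and -2.66 with a pseudocount of 1 and -7.65 and -6.83 in limma-voom. The adjusted p of the 12 genes in limma lay between 1.3e-08 for Trib3 and 4.7e-05 for Mt2.

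**Figure D1:**
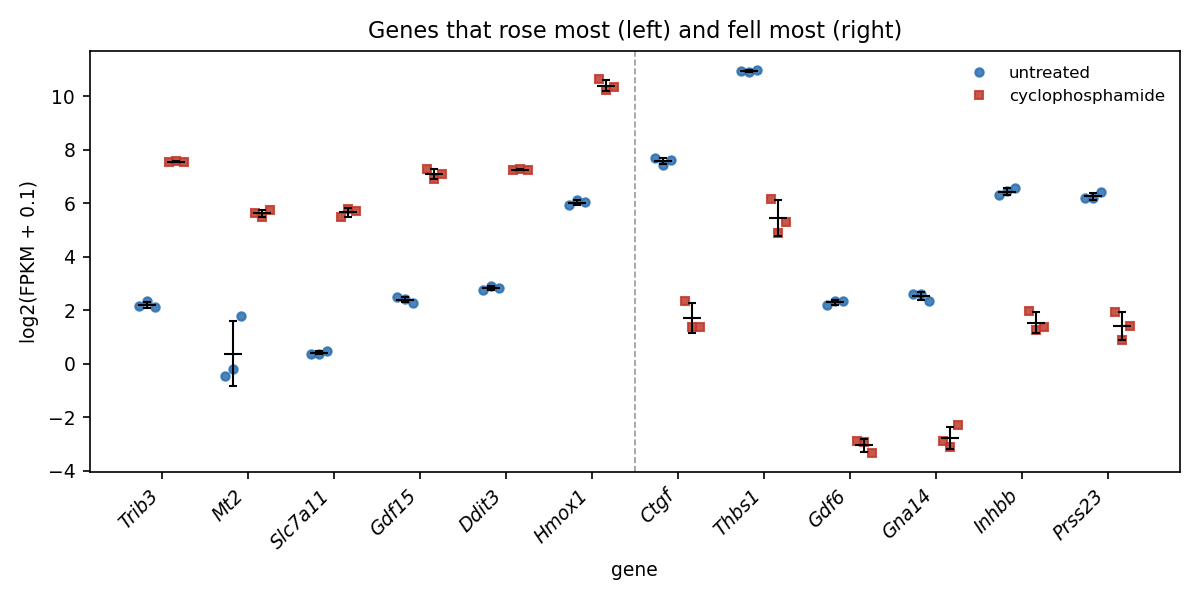
Level of each gene in every library as log2(FPKM + 0.1) on the vertical axis, for the 6 genes that rose most and the 6 that fell most on the horizontal axis. Circles are untreated and squares cyclophosphamide libraries, black marks the mean and SD of 3 libraries, and the groups do not overlap for any of the 12 genes.

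In the table's coordinates, read as GRCm38, Trib3 (ENSMUSG00000032715) lies on chromosome 2 from 152337422 to 152344032 and Slc7a11 (ENSMUSG00000027737) on chromosome 3 from 49892526 to 50443614. Ctgf (ENSMUSG00000019997) lies on chromosome 10 from 24595442 to 24598683 and Thbs1 (ENSMUSG00000040152) on chromosome 2 from 118111876 to 118127133. All 4 are annotated as protein-coding.

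Across the transcriptome, 10229 of 14755 genes tested changed (limma, Benjamini-Hochberg adjusted p under 0.05), 4913 higher and 5316 lower. The balance depended on the scaling, with 5522 higher and 4795 lower under upper-quartile scaling, and 5230 higher and 5035 lower with scaling to total reads. The changed genes were 69.3% of those tested, with a median log2 fold change of -0.02 over all genes and a median SE of 0.12. At least 2-fold changes were found for 1475 higher and 2455 lower genes, and at least 8-fold changes for 60 higher and 135 lower genes. Among genes named by the rule, a pseudocount of 1 also shrank the fold changes of Bmpr1b (-2.73), Pmaip1 (2.97), Ifit2 (-1.11), Esam (1.15), Upk3b (-0.66), Gdf9 (1.28) and Ooep (0.38) by over 1.5-fold.

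Genes of serine synthesis rose modestly. Phgdh, the first enzyme of the pathway, rose by 0.36 ± 0.07 on the log2 scale (limma, adjusted p = 0.0015), Psat1 by 0.35 ± 0.07 (0.0019) and Psph, the last step, by 0.84 ± 0.07 (1.7e-05). The mitochondrial serine hydroxymethyltransferase gene Shmt2 rose by 0.75 ± 0.06 (2.1e-05), while the cytosolic Shmt1 had a log2 fold change of -0.04 ± 0.10 (limma, adjusted p = 0.76), whose sign was positive under upper-quartile scaling. The neutral amino acid transporter Slc1a4 and the glycine transporter Slc6a9 rose by 2.76 ± 0.07 and 2.77 ± 0.09. Of 21 measured members of the serine and single-carbon list, 13 rose and 4 fell, with a median of 0.36. The members that fell were Gldc (-2.17 ± 0.19), Aldh1l1 (-1.07 ± 0.14), Sdsl (-0.84 ± 0.10) and Mthfd1l (-0.67 ± 0.11). The list as a whole ranked higher (camera, adjusted p = 0.037), and this call was lost at adjusted p = 0.19 with an estimated correlation. That estimate (-0.02) lay below the preset 0.01, so a higher correlation did not remove the call. For this and all other lists, the counts adjusted over the list alone were equal to those given, except where stated.

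Genes of glutathione metabolism moved both ways, and those that rose included its synthesis. Gclc, the catalytic subunit of the rate-limiting enzyme, rose by 3.01 ± 0.06, Slc3a2, the partner of Slc7a11 in the cystine importer, by 2.91 ± 0.08, and Chac1, which degrades glutathione, by 3.33 ± 0.07. Of 29 measured members of the glutathione list 13 rose and 13 fell (median 0.23, camera, adjusted p = 0.24). Gpx4, the glutathione peroxidase that reduces lipid peroxides, fell by 0.41 on the log2 scale (SE 0.08, limma, adjusted p = 0.0020). Among 20 measured ferroptosis suppressors 8 rose, including Slc7a11 and Nqo1 (3.08 ± 0.12), and 7 fell (median 0.01, camera, adjusted p = 0.66). Among 22 measured ferroptosis drivers 12 rose, including Hmox1 (4.38 ± 0.12), and 7 fell (median 0.27, camera, adjusted p = 0.24). Acsl4, which places polyunsaturated fatty acids into phospholipids, rose by 0.39 ± 0.10 (limma, adjusted p = 0.0070), while Far1 (-1.77 ± 0.08) and Lpcat3 (-1.28 ± 0.06) fell.

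The iron storage gene Fth1 rose and the gene of the iron uptake receptor fell. Fth1, the ferritin heavy chain, rose by 1.55 ± 0.20 (limma, adjusted p = 0.00019) and Tfrc, the transferrin receptor, had a log2 fold change of -1.09 ± 0.12 (9.1e-05). Fbxl5, an iron-sensing ubiquitin ligase subunit, rose by 1.43 ± 0.08 and the mitochondrial iron importer Slc25a37 by 1.15 ± 0.07. In the iron-handling list of 23 measured members, 10 rose and 6 fell (median 0.05, camera, adjusted p = 0.21).

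Targets of the transcription factors ATF4, NRF2 and p53 rose together. In the ATF4 list, which covers the response to amino acid shortage, 26 of 27 measured members rose, including Chac1 and Sesn2 (2.80 ± 0.07), with a median of 1.53, and Nupr1 fell (-0.74 ± 0.11). Of 24 measured NRF2 targets, which act against oxidative stress, 21 rose, including Srxn1 (4.16 ± 0.07), with a median of 1.78, and Me1 (-0.83 ± 0.17) and Gstm1 (-0.31 ± 0.07) fell. Of 30 measured p53 targets 27 rose (median 1.33), among them Mdm2 (2.48 ± 0.15), Ddit4 (3.25 ± 0.09) and the cell cycle inhibitor Cdkn1a (1.22 ± 0.10), and Sesn1 fell (-0.53 ± 0.10). All 3 lists ranked higher than other genes by camera, with adjusted p = 1.8e-11 for ATF4, 2.2e-09 for NRF2 and 8.7e-10 for p53. These calls were lost at adjusted p = 0.11, 0.17 and 0.18 with an estimated correlation.

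Genes of the unfolded protein response moved both ways. In the unfolded protein response list of 19 measured members 13 fell, including Derl3 (-1.91 ± 0.08), and 4 rose, namely Herpud1 (1.28 ± 0.11), Dnajb9 (1.07 ± 0.11), Sel1l (0.49 ± 0.08) and Hspa5 (0.27 ± 0.09), with a median of -0.58 (camera, adjusted p = 0.058). In the heat shock list 9 of 16 rose and 5 fell (median 0.31, camera, adjusted p = 0.33), with Hsph1 at 1.12 ± 0.08 and Hspb1 at -1.15 ± 0.14. Of 25 measured apoptosis genes 12 rose and 8 fell, with Pmaip1, a p53-induced death gene, at 3.77 ± 0.16 and Bok at -1.29 ± 0.07. The median of that list was -0.11, while its mean (0.27) and the direction of camera were upward (adjusted p = 0.66).

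Genes of the cell cycle fell. All 31 measured mitosis genes fell, with a median of -1.79, among them the proliferation marker Mki67 (-2.64 ± 0.10) and the mitotic kinase Cdk1 (-1.75 ± 0.07). In the DNA replication list 24 of 34 fell, including Uhrf1 (-2.37 ± 0.14) and the helicase subunit Mcm6 (-1.15 ± 0.08), and the licensing factor Cdt1 rose (0.87 ± 0.11), with 2 higher adjusted over the list alone. Of 28 genes of crosslink and recombination repair 18 fell and 4 rose, such as Rad51d (1.16 ± 0.07). Of 10 measured replication-dependent histone genes 8 fell, with Hist1h1c at -2.69 ± 0.14 and Hist1h2bc at -1.81 ± 0.13, and reads of these near-identical genes without poly(A) tails are uncertain. By camera the lists ranked lower at adjusted p = 1.7e-11 for mitosis, 1.8e-05 for replication, 0.013 for repair (median -0.71) and 0.012 for histones (median -1.26). The calls were lost at adjusted p = 0.24, 0.19, 0.19 and 0.39 with an estimated correlation, although the estimate for repair (-0.003) lay below the preset 0.01.

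Genes that mark granulosa cells fell. In the granulosa identity list 15 of 19 measured members fell, with a median of -1.22, including the BMP receptor Bmpr1b (-3.73 ± 0.12), the inhibin subunit Inhba (-2.67 ± 0.09) and the FSH receptor Fshr (-1.17 ± 0.24, limma, adjusted p = 0.0029). Foxl2, a transcription factor that maintains granulosa fate, had a smaller change of -0.45 ± 0.07 (limma, adjusted p = 0.00087), and Kitl (0.96 ± 0.07) and Grem1 (0.26 ± 0.10) rose. The list ranked lower (camera, adjusted p = 0.00020), a call lost at adjusted p = 0.19 with an estimated correlation. Genes spanning at least 128.9 kb, which include Bmpr1b and Fshr and, outside this list, Gna14 and Mylk, had a median log2 fold change of -0.84 as a class. Cyp19a1, the aromatase gene, had 3 reads in the untreated and 1 in the cyclophosphamide libraries, and a difference was not detectable at this depth.

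Steroidogenic genes diverged. Star, which carries cholesterol into mitochondria, rose by 4.19 ± 0.16, while Hsd17b1, which makes oestradiol from oestrone, fell (-1.91 ± 0.07). Of 16 measured members of the steroidogenesis list 3 rose, namely Star, Stard3 (0.72 ± 0.11) and Nr5a1 (0.33 ± 0.08), and 8 fell (median -0.38, camera, adjusted p = 0.12). Of 23 cholesterol synthesis genes 14 fell and 0 rose, with Sc5d at -1.19 ± 0.08. Their median was -0.81 (camera, adjusted p = 0.0014), with adjusted p = 0.55 with an estimated correlation.

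Matrix genes fell as a group. Of 26 measured members 21 fell and 0 rose, including Ctgf, Thbs1, tenascin gene Tnc (-2.97 ± 0.13) and fibrillin gene Fbn1 (-2.22 ± 0.12), with a median of -1.02 (camera, adjusted p = 2.2e-06, and adjusted p = 0.19 with an estimated correlation). Fbn1 also belongs to the class of genes with a long span. Some markers of matrix-producing cell types also fell. Of 5 measured theca and stroma markers 1 rose and 2 fell. Those that fell, Col1a1 (-1.96 ± 0.15) and Col3a1 (-1.75 ± 0.11), are themselves members of the matrix list. Of 9 smooth muscle and pericyte markers 6 fell and 2 rose. Neither marker list passed the threshold in camera (adjusted p = 0.51 and 0.22). In the list of inflammatory and secreted factors 5 of 13 rose, with Ptgs2 at 3.03 ± 0.09, and 5 fell, with Plau at -3.41 ± 0.16. Its median was -0.13, while camera pointed upward (adjusted p = 0.80). Of 13 measured interferon genes 9 fell, including Ifit2 (-2.12 ± 0.18), and Oasl2 (2.10 ± 0.08) and Oasl1 (1.64 ± 0.24) rose (median -0.84, camera, adjusted p = 0.19).

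Other lists moved in both directions. Among 21 immediate early genes 11 rose, including Fosl1 (3.93 ± 0.09) and Atf3 (3.69 ± 0.09), and 6 fell (median 0.70, camera, adjusted p = 0.083). Among 25 aldehyde and drug conjugation genes 8 rose, or 10 adjusted over the list alone, and 14 fell, with the glutathione transferase Gsta4 at 3.73 ± 0.09 and the efflux pump Abcb1b at -2.18 ± 0.11 (median -0.31, camera, adjusted p = 0.43). In the glycolysis and hypoxia list, where Aldoa appears under 2 gene IDs, 7 of 23 rose, with Vegfa at 3.72 ± 0.06 and the glucose transporter Slc2a1 at 2.09 ± 0.06, and 10 fell. Its median was -0.14 and its mean 0.16 (camera downward, adjusted p = 0.86). In the lysosome and autophagy list 8 of 23 rose, with Sqstm1 at 1.90 ± 0.13 and Gabarapl1 at 1.50 ± 0.07, and 8 fell, or 9 adjusted over the list alone (median 0.09, camera, adjusted p = 0.43).

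Of 12 measured protein-coding genes of the mitochondrial genome 9 fell, such as mt-Nd3 (-1.57 ± 0.07) and mt-Co2 (-1.38 ± 0.10), with a median of -1.33 (camera, adjusted p = 0.0037, and adjusted p = 0.43 with an estimated correlation). The most abundant, mt-Co1, had a log2 fold change of 0.50 ± 0.47 (limma, adjusted p = 0.36). Its level was 6818 ± 931 FPKM in untreated and 9579 ± 109 in cyclophosphamide libraries (SD, n = 3). The moderated SE is wider than the spread of these values, so the missing call does not show that mt-Co1 was unchanged. The share of reads on the mitochondrial protein-coding genes was 1.75% to 2.19% in untreated and 1.92% to 2.10% in cyclophosphamide libraries. The share of reads on mitochondrial ribosomal RNA was 0.0235% to 0.0303% in untreated and 0.0700% to 0.150% in cyclophosphamide libraries. Near-identical copies in the nuclear genome make the reads of these genes uncertain.

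**Figure D2:**
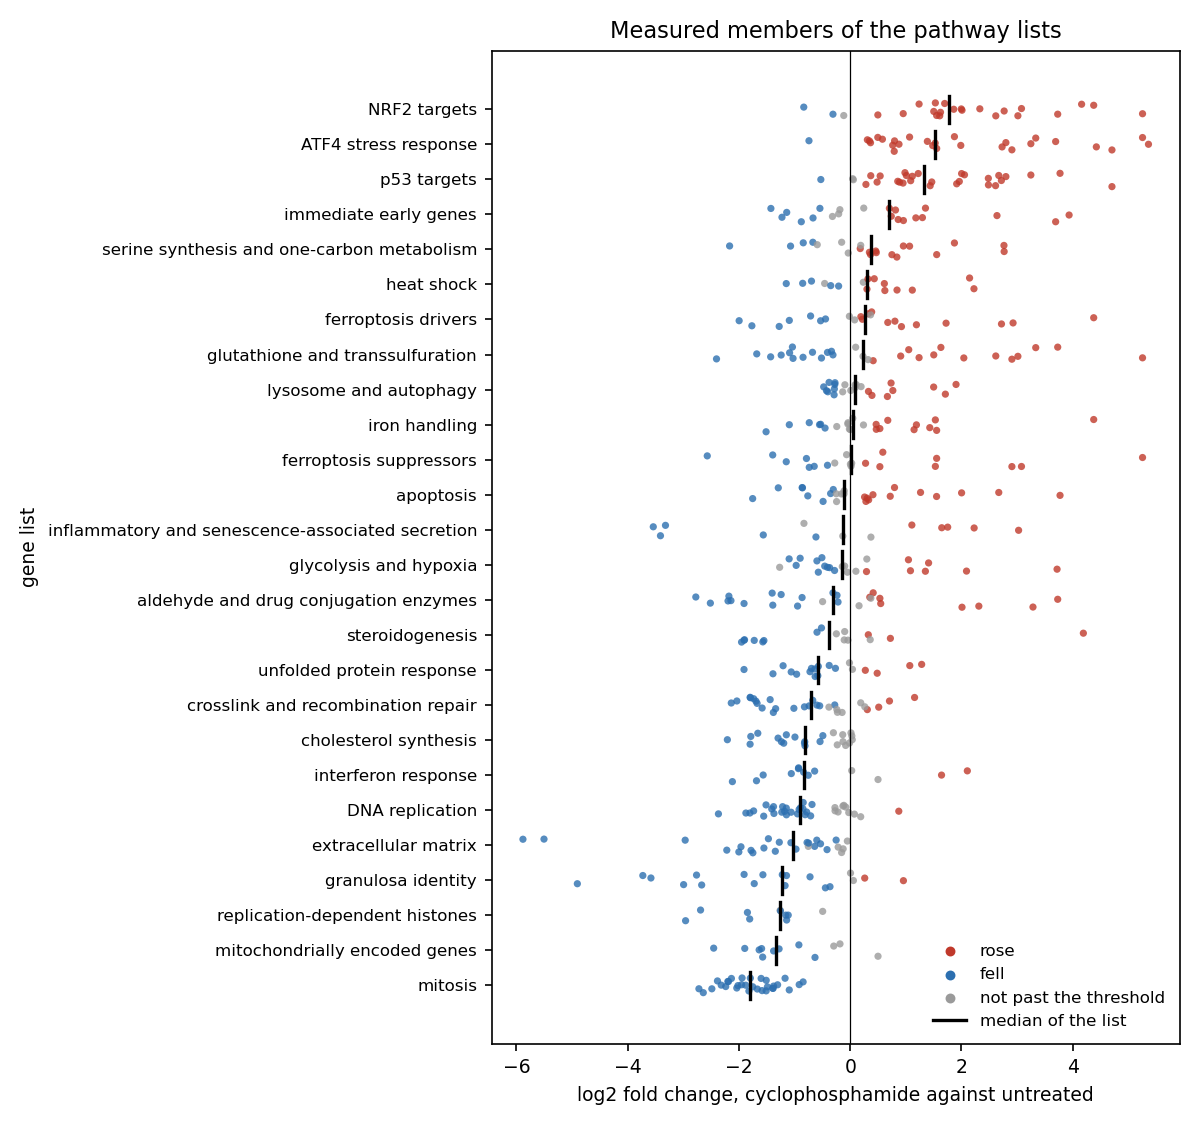
Log2 fold change of every measured member (points, horizontal axis) of the 26 pathway lists (vertical axis, ordered by median), cyclophosphamide against untreated, n = 3 in each group. Colour marks members that rose, fell or did not pass limma's threshold, and black bars mark list medians, from 1.78 for NRF2 targets to -1.79 for mitosis.

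Markers of other cell types moved unevenly. In camera 0 of 3 testable marker lists passed the threshold and 1 was lower at an unadjusted p under 0.05, while fry, which does not compare a list with other genes, called all 3. The surface epithelium list (5 of 6 fell, median -1.21, camera, adjusted p = 0.072, and adjusted p = 0.0496 under upper-quartile scaling) included Upk3b (-2.22 ± 0.19) and Krt8 (-1.16 ± 0.14). The smooth muscle and pericyte list (2 of 9 rose and 6 fell, median -1.15, camera, adjusted p = 0.22) included Notch3 (1.86 ± 0.14) and Mylk (-2.35 ± 0.11). The theca and stroma list (1 of 5 rose and 2 fell, camera, adjusted p = 0.51) included Col3a1 and Col1a1, given above. Of 4 measured macrophage markers Csf1r (1.93 ± 0.11), Cd14 (1.32 ± 0.21) and Cd68 (1.08 ± 0.14) rose and Lyz2 fell (-0.95 ± 0.31), while C1qa, C1qb, C1qc, Tyrobp and Fcer1g together held 54 reads in untreated and 20 in cyclophosphamide libraries. Of 4 endothelial markers Esam rose (2.40 ± 0.16), and of 3 oocyte markers Gdf9 (2.32 ± 0.15, 41 to 253 reads) and Ooep (0.99 ± 0.29, 34 to 78 reads) rose. The Ooep call was lost without any 1 of 4 libraries. Oocyte markers below the filter held few reads, from untreated to cyclophosphamide libraries 2 to 19 for Padi6, 1 to 11 for Bmp15 and 6 to 11 for Dazl. Reads went from 0 to 9 for Zp2, 0 to 7 for Zp3, 0 to 6 for Oosp1 and 0 to 3 for Nlrp5. Zp1 went from 1 to 6, and Figla had 0 reads in both groups. No lymphocyte or erythroid marker passed the filter on low counts.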

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

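The tests with pseudocounts of 0.5 and 1 and with scaling to total reads were chosen only after the result was seen, and the split tests were set before theirs. With a minimum of 2-fold the count of changed genes was 3930 (1475 higher and 2455 lower). In all other alternatives it stayed between 8377 (adjusted p under 0.01) and 10373, and between 9326 and 10109 when 1 library was left out. limma-voom on recovered reads called 10373 genes, 10012 of them shared in the same direction. Upper-quartile scaling moved the median log2 fold change of all genes to 0.067. Camera with an estimated correlation called 0 pathway lists higher and 0 lower, and 3 higher and 2 lower at an unadjusted p under 0.05. Few residual degrees of freedom leave hardly any list able to pass after adjustment in that form. Its 0 calls therefore cannot tell how much correlation between genes matters. With the preset correlation 4 to 5 pathway lists were higher and 7 to 9 lower. The stricter filter left the histone list under 5 members, so it was not tested, and the added calls were the unfolded protein response list (lower) and the immediate early list (higher). Fry, which does not compare a list with other genes, called 12 pathway lists higher, 11 lower and 3 marker lists. The marker lists called were 1 under upper-quartile scaling and 0 to 1 when a library was left out, with 1 without cyclophosphamide replicate 1. The first principal component held 56.0% with no filter. Shmt1 was reversed at 0.057 under upper-quartile scaling, 0.010 with scaling to total reads and 0.014 without untreated replicate 2, and leaving out each library gave -0.10 to 0.014. The cause was not tested. With the replicate block, 9915 genes were called, and same-numbered libraries did not deviate together (correlations -0.08, 0.01 and -0.02).

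Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many as 10229 genes, and the highest of the others gave 0 in limma (34 to 128 genes at an unadjusted p under 0.05). For camera with the preset correlation 1 of the 10 splits gave as many as 12 pathway lists, while the other splits gave 9 to 11. So few splits cannot give a share under 0.05. In a mixed split the treatment difference also lies inside the groups and widens their spread, so its 0 gene calls lend no support to the real split. A mixed split keeps part of the treatment difference between its groups, so list counts with the preset correlation were not specific to the real split. The planned edgeR and DESeq2 tests were not run: limma was used for the deposited FPKM, and limma-voom was the only count-based test run on the recovered reads. Low-level genes such as Gdf6 and Gna14 are limited by depth in the size of their fold change.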

Other observations

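The tests of ribosomal genes, transcription factor families, exonic length, expression level, span, mitochondrial content, macrophages, YAP and TAZ, shared list members and the minichromosome maintenance complex were chosen only after the result was seen, while those of GC content and carry-over were set before theirs. Genes of the cytoplasmic ribosome rose slightly, with 60 of 78 higher and 0 lower and a median log2 fold change of 0.50. Camera gave an adjusted p of 7.8e-08, and an adjusted p = 0.49 with an estimated correlation. Among 14 families of transcription factors with at least 10 measured members, the ZBTB zinc finger family had the smallest p, with 27 of 42 higher and 6 lower and a median of 0.54 (camera, adjusted p = 0.0020, and adjusted p = 0.15 with an estimated correlation). The MYB (16 of 22 higher, camera, adjusted p = 0.018), bZIP (23 of 41 higher, adjusted p = 0.037) and C2H2 families (192 of 448 higher, adjusted p = 0.037) also ranked higher, and lost the call at adjusted p = 0.62, 0.76 and 0.76 with an estimated correlation.

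The 10% of protein-coding genes with the longest genomic span (at least 128.9 kb) had a median log2 fold change of -0.84, with 149 higher and 874 lower of 1269, against 0.01 for all shorter genes. Bias from exonic length is argued against, since the weakest difference over 5 bins of exonic length was -0.70 (bootstrap interval -0.94 to -0.56), and low expression likewise, at -0.57 (-0.72 to -0.42) over 5 bins of FPKM. GC content stays open: the bin of highest GC had -0.30 (-0.58 to -0.08), although the other 4 lay between -0.94 and -0.84. That drug lesions block elongation in long genes stays open: the partial rank correlation of fold change with span above the median span was -0.25, but this restates the fall of the longest genes and decides nothing. Slc7a11 rose despite its long span, and a shared function of long genes was not tested.

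Mitochondrial ribosomal RNAs rose (mt-Rnr1 3.01 ± 0.26, mt-Rnr2 1.16 ± 0.27) while most mitochondrial messengers fell, such as mt-Cytb (-1.90 ± 0.17). The messengers did not fall uniformly. The log2 ratio of mt-Co1 to mt-Cytb was 2.05 ± 0.08 (SD, n = 3) in untreated and 4.44 ± 0.17 in cyclophosphamide libraries, a difference of 2.40. This argues against a uniform loss of mitochondrial RNA as the whole account. The pair was chosen after the fold changes were seen, and a ratio between messengers does not measure content. A lower mitochondrial content therefore stays open. Carry-over of RNA without a poly(A) tail may play a part: 4 nuclear small RNAs had a median of 2.18 (3 rose and 1 fell) and ranged from -1.45 to 2.83. So few RNAs cannot decide it. In the same direction, 14 of 23 small nucleolar RNAs rose and 0 fell. A change in mitochondrial transcription or processing was not tested.

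Macrophages in the treated cultures could bring the higher Csf1r, Cd68 and Cd14. Against this, the abundant macrophage genes C1qa, C1qb, C1qc, Tyrobp and Fcer1g together held 1.57% of the reads of Csf1r in the cyclophosphamide libraries, 20 against 1271, and were fewer than in the untreated libraries (54). Expression of these markers in the granulosa cells themselves remains a hypothesis that was not tested.

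The fall of Ctgf prompted the hypothesis of lower activity of the transcription coactivators YAP and TAZ. In a list of 22 of their targets written after the top genes were seen, 13 of 21 measured members fell and 6 rose. Without Ctgf the list ranked lower (camera, p = 0.029, adjusted p = 0.050 over 34 lists), but not with an estimated correlation (adjusted p = 0.35). The 34 lists include reduced copies of lists that had already passed, which eases the adjustment, so the adjusted value is not strict. Members that fell included Crim1 (-2.44 ± 0.08), Ankrd1 (-2.02 ± 0.11), Amotl2 (-1.85 ± 0.08) and Axl (-1.17 ± 0.08). Those that rose included Gadd45a (2.72 ± 0.10) and F3 (1.33 ± 0.09), and Cyr61, a classical target, had a log2 fold change of -0.15 ± 0.14. The data leave this undecided. A further hypothesis was that members shared with the ATF4 list carry the rise of the serine list. Without them 9 of 17 members rose and 4 fell, with a median of 0.19 (bootstrap interval -0.59 to 0.84, camera p of 0.12 and adjusted p = 0.17 over 34 lists), which may reflect the smaller list as much as the shared genes. The ATF4, NRF2 and p53 lists without shared members still ranked higher by camera, with adjusted p = 1.5e-08, 9.9e-09 and 2.1e-08, each with adjusted p = 0.12 with an estimated correlation. The 6 genes of the minichromosome maintenance complex had a median of -0.91, and 5 fell (camera, adjusted p = 0.014, and adjusted p = 0.33 with an estimated correlation).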
